A study of Homo sapiens with 18 samples.

How the data were processed

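RNA was measured in 18 xenograft tumours, 1 array per tumour, on the Affymetrix HG-U133A array. Per the labels, human head and neck squamous carcinoma tumours of a radioresistant and a radiosensitive line were grown in nude mice to 150 to 200 mm3, left untreated or given 3 Gy, and collected 5 or 24 h later. Each group had 5 animals, and 3 tumours per group were profiled, with 6 µg of total RNA per array. The labels number the tumours from 1 to 3 in each group and state no pairing between groups.

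The deposited values are the authors' MAS5 signals, an intensity per probe set on a linear scale. The authors scaled them so that the 2% trimmed mean was 500 on every array, which was checked on the values; the MAS5 version and its settings are not stated. No raw probe intensities were used. The deposited run records hold no expression values, and only the fluidics station and the start of the wash were read from them, as technical labels. For arrays, the number of tumours limits the precision of each value.

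The 22283 probe sets include 68 controls, which were left out. The table that pairs probe sets with genes gave 1 symbol for 19065 probe sets, several for 1043 and none for 2107. Genes without a name in that table were not analysed. Signals were used as log2(signal + 24.7), where the offset was the 10th percentile of all values, so that folds of genes with low signal are smaller than the ratio of their signals. Probe sets were kept when their mean over all arrays was at or above the 40th percentile of probe-set means, which left 13329. A gene was represented by its brightest kept probe set with only that symbol, which gave 8369 genes tested.

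One limma model (3.58.1, in R 4.3.3) was fitted to all 18 arrays, with a mean for each of the 6 groups, lmFit and eBayes with an intensity trend. All groups shared 1 estimate of the spread, which gave 19.2 degrees of freedom and a median SE of 0.282 on the log2 scale, or 0.399 for a difference of responses. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the kept probe sets, with a threshold of 0.05. A permutation of 3 tumours against 3 cannot give a two-sided p below 0.1, so none was used for single genes. The 9 comparisons were the line difference in untreated tumours, at 5 h and at 24 h, the response of each line at each time, and the difference between both lines' responses at each time. A difference of responses is the response of the radioresistant tumours minus that of the radiosensitive tumours.

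Gene lists that fit the tissue and the treatment, 21 lists of 503 genes, were fixed together with the comparisons, thresholds and alternatives before the data were examined. Of their genes, 385 were measured, and some genes belong to more than 1 list. The lists were interferon-stimulated genes, a 7-gene interferon-related radioresistance signature, MHC class I antigen presentation, interferon-gamma response, p53 targets, G2/M and mitosis, G1/S and DNA replication, DNA double-strand break repair, apoptosis, hypoxia, keratinocyte differentiation, mesenchymal and invasion genes, NF-kappa-B inflammatory genes, immediate-early and heat-shock genes, NRF2 oxidative stress genes, glycolysis and oxidative phosphorylation. Markers of fibroblasts, endothelium, macrophages and leukocytes, and skeletal muscle and fat completed them. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, again with an estimated correlation, and with fry, which tests whether a list's genes move, on balance, one way. Members were counted over all genes tested and with p-values adjusted over the list alone. Members of a list are called risen or fallen where they passed over all genes.

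Genes were named by a rule. In each comparison it took the 8 largest rises and 8 largest falls among genes that passed and whose tumours did not overlap; where fewer than 5 passed, it took all of them and the 5 smallest unadjusted p-values. It added up to 4 passing members of each list past camera, 2 to 4 members with the largest change for each list described, and in every comparison a set of interferon, p53 and mitotic genes. Of that set, MDM2 and BAX had no kept probe set.

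The tests were tried on simulated data for the untreated line comparison over its 8369 genes. Of genes changed 1.5-fold, 4.48% were recovered, of those changed 2-fold 34.3%, and of those changed 4-fold 81.8%, with 2 false calls among 82. In the same simulation camera called a shifted list, and 3 of 100 unshifted lists had a p below 0.05. The simulated genes were independent, so this cannot test the preset correlation for lists whose genes move together. In the data the estimated correlation was 0.234 for interferon-stimulated and 0.145 for keratinocyte differentiation genes.

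Alternatives were quantile normalization, no offset, 4 times the offset, no filter, a filter at the 60th percentile, the tumour number as a block, only the groups compared, no intensity trend, array weights, the mean of a gene's probe sets, and leaving out each array in turn. The alternatives chosen after seeing the data were leaving out both arrays that stood apart, the wash run or fluidics station as a block, and the first wash run alone. A block for chip lot or scan day was planned and not run, since all arrays were scanned on 1 day and no lot was recorded. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.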

Results

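The series profiled gene expression in xenograft tumours of the human head and neck squamous carcinoma line SCC-61 and of its radioresistant derivative nu61, before and after ionizing radiation. Tumours are named here as the sample titles give them, radioresistant and radiosensitive. There were 3 tumours in each of 6 groups, which were radioresistant and radiosensitive tumours that were untreated, 5 h after 3 Gy or 24 h after 3 Gy. The measure was the MAS5 signal of each probe set, and 8369 genes were tested. Median signals lay between 188 and 300 on the 18 arrays, and the mean correlation of an array with the other arrays of its group lay between 0.843 and 0.945.

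A pair of radiosensitive arrays stood apart from the rest. In untreated replicate 2, the signal at the 3' end of GAPDH was 36.1 times that at the 5' end, against 0.978 to 1.73 on the other 17 arrays, and the same ratio for ACTB was 41.7, against 2.61 to 5.46. A high ratio is a sign of degraded RNA. In replicate 2 at 24 h, the log2 range between the 10th and 90th percentiles of signal was 4.8, against 5.36 to 6.41 on the other 17, and its median correlation with other arrays was 0.804, against 0.875 to 0.925. The ACTB ratio also differed by line. In untreated tumours it was 2.76 to 3.04 in the radioresistant and 3.62 to 41.7 in the radiosensitive line. At 5 h it was 2.61 to 3.58 and 5.13 to 5.46, and at 24 h 3.33 to 4.19 and 3.01 to 3.41. The arrays were washed in 3 runs on 2 fluidics stations. The first run held 3 radioresistant and 2 radiosensitive untreated arrays and 2 radioresistant arrays of 5 h. The second held 1 radioresistant and 3 radiosensitive arrays of 5 h and 3 radioresistant arrays of 24 h. The third held 2 radiosensitive arrays of 24 h, and a pair of radiosensitive arrays had no usable record.

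**Figure D1:**
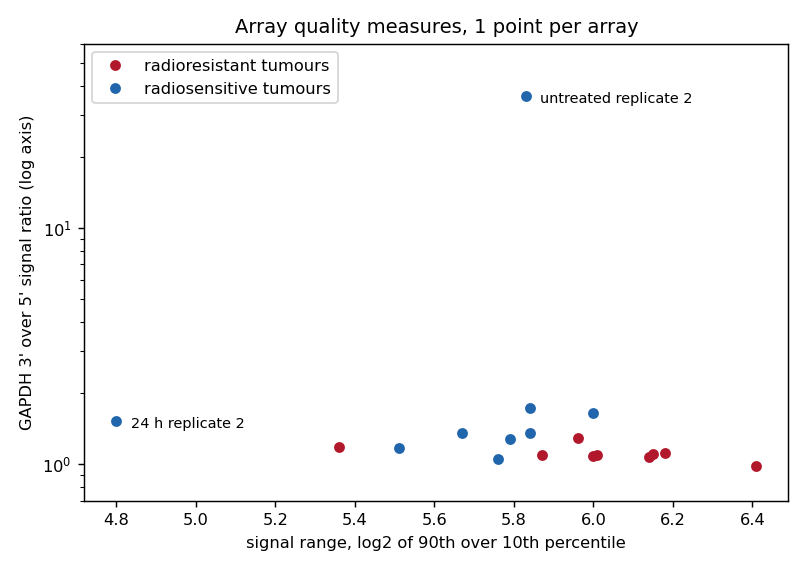
Signal range (log2 of the 90th over the 10th percentile, horizontal axis) against the GAPDH 3' over 5' signal ratio (vertical log axis), with 1 point per array and colours for both lines. Radiosensitive untreated replicate 2 lies at a ratio of 36.1 and radiosensitive 24 h replicate 2 at a range of 4.8, apart from the other arrays.

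The first comparison asked how radioresistant and radiosensitive tumours differed before irradiation. Genes induced by interferon were the largest group of differences, and they were higher in radioresistant tumours. IFI27 had a signal of 13280 ± 975 (SD, n = 3) in radioresistant and 1404 ± 206 in radiosensitive tumours, 9.36-fold higher (log2 3.23, SE 0.253, limma adjusted p = 1.05e-06). ISG15, a ubiquitin-like protein induced by interferon, was 6.2-fold higher (5298 ± 1330 against 821 ± 99.7, adjusted p = 5.09e-05), and MX1, an antiviral GTPase, 6.11-fold (adjusted p = 2.68e-05). Among the lower genes, STK26, a protein kinase, was 6.14-fold lower (147 ± 50.3 against 1003 ± 80.2, adjusted p = 1.62e-05), and S100A7, a protein of differentiating keratinocytes, 2.69-fold lower (10920 ± 537 against 29480 ± 2670, adjusted p = 0.000141).

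Of 43 interferon-stimulated genes measured, 25 were higher in untreated radioresistant tumours and none lower, or 34 with p-values adjusted over the list alone. Of the list 42 lay above 0, with a median log2 difference of 1.26 (camera adjusted p = 3.74e-44; adjusted p = 0.00494 with an estimated correlation). IFI44L differed most, with log2 5.06, although its radiosensitive signal of 54.3 ± 35.6 was near the floor, so its 33.3-fold difference is uncertain. IFIT1 was 8.35-fold higher (adjusted p = 0.000141), DDX60 6.07-fold, BST2 5.49-fold (adjusted p = 0.00413), IFI44 3.96-fold and IFIT3 2.7-fold (adjusted p = 0.00751). The 7-gene interferon-related radioresistance signature had 6 measured genes, all also in the longer list. All 6 were higher, and 6 adjusted over the list alone, with a median of 2.30 (camera adjusted p = 2.73e-16; adjusted p = 0.0155 with an estimated correlation). That signature goes back to work on these lines, so its count is not independent evidence. OAS1, one of its members, was 2.22-fold higher (adjusted p = 0.0237), a call kept with 2 of the 6 arrays left out in turn. Radiosensitive untreated replicate 2, the array with the high 3' to 5' ratio, is in this comparison, and without it the median of the interferon-stimulated genes was 1.18.

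Genes of MHC class I antigen presentation, which display peptides to T cells, were also higher. Of 16 measured, 6 were higher and none lower, or 8 higher and 1 lower when adjusted over the list alone, with a median log2 difference of 0.54 (camera adjusted p = 3.4e-06; adjusted p = 0.0473 with an estimated correlation). HLA-B was 2.06-fold higher (21320 ± 3690 against 10240 ± 804, adjusted p = 0.00479), HLA-G 2.16-fold and HLA-F 1.79-fold. PSMB8, a subunit of the immunoproteasome, was 5.48-fold higher (adjusted p = 0.0347), with a radiosensitive signal of 231.2 ± 245. The interferon-gamma response list did not pass (median -0.19, adjusted p = 0.908), although 1 of its 13 members, the chemokine CXCL10, was 2.71-fold higher (adjusted p = 0.0243). PSMB8 and CXCL10 each kept their calls with 2 of the 6 arrays left out in turn, and HLA-G with 3.

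Keratinocyte differentiation genes moved in both directions. Of 32 measured, 2 were lower and 3 higher, or 12 lower and 4 higher when adjusted over the list alone, and the median log2 difference was -0.44 (camera adjusted p = 0.0066). This call was lost with an estimated correlation (adjusted p = 0.59). It was also lost with quantile normalization (median -0.17, adjusted p = 0.2) and without radioresistant untreated replicate 2 (adjusted p = 0.0711). S100A7 was among the lower genes, while the serpins SERPINB3 and SERPINB4 were 2.5-fold and 3.41-fold higher (adjusted p = 0.01 and 0.00788) and LCN2, a secreted iron-siderophore binding protein, 2.29-fold higher (adjusted p = 0.0177).

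Outside the lists, the largest falls were those of PDLIM4 (7.52-fold lower, adjusted p = 0.000225), the keratin KRT76 (6.45-fold lower, 45.63 ± 19.2 against 428.6 ± 123, adjusted p = 0.000141), STK26 and the small GTPase RAP2C (5.27-fold lower, adjusted p = 0.000298). PIDD1, a p53-induced death-domain protein outside the p53 list, was 4.2-fold lower (adjusted p = 0.00415), SH3YL1 3.8-fold, the phospholipase PLCB3 3.7-fold and MAL 3.22-fold (adjusted p = 0.022). PLCB3 kept its call with 2 of the 6 arrays left out in turn and MAL with 3. The NRF2 oxidative stress list did not pass as a whole (median -0.07, adjusted p = 0.62), with 2 members higher, AKR1C2 and AKR1C3, and 3 lower, among them ALDH3A1 and AKR1B10. AKR1C3 kept its call with 2 of the 6 arrays left out in turn and AKR1B10 with 3. None of the 19 measured genes of the p53 list passed, and its median was -0.03 (adjusted p = 0.908). CDKN1A, the p53-induced cell cycle inhibitor, had a log2 difference of -0.06 (adjusted p = 0.867), GADD45A -0.08 and FAS 0.34. Among mitotic genes CCNB1 had a log2 difference of 0.02 and PLK1 0.33, and neither passed.

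None of the other lists passed in untreated tumours. Median log2 differences were 0.02 for G2/M and mitosis, -0.12 for G1/S and DNA replication, -0.01 for DNA double-strand break repair, 0.08 for apoptosis, 0.19 for hypoxia (adjusted p = 0.0517), 0.21 for mesenchymal and invasion genes, -0.04 for NF-kappa-B inflammatory genes, 0.36 for immediate-early and heat-shock genes, 0.12 for glycolysis and 0.06 for oxidative phosphorylation. Within the first wash run, without radiosensitive untreated replicate 2, the medians were -0.04 for mesenchymal and invasion genes, 0.07 for immediate-early and heat-shock genes and 0.01 for G1/S and DNA replication. Among the genes of these lists, the collagenase MMP1 was 1.87-fold lower, the hexokinase HK1 2.23-fold lower and the prolyl hydroxylase P4HA2 1.83-fold higher. Of the 6 arrays left out in turn, MMP1 and HK1 kept their calls with 1 and P4HA2 with 3. Markers of other cell types were read by human probe sets, while host cells of a nude mouse are murine. Their medians were -0.13 for fibroblasts (9 genes; DCN was 3.12-fold lower, adjusted p = 0.000191), -0.59 for endothelium (6 genes), -0.17 for macrophages and leukocytes (7 genes) and -0.10 for skeletal muscle and fat (9 genes), and none passed.

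In all, limma called 147 genes between untreated radioresistant and radiosensitive tumours, 81 higher and 66 lower, of which 56 and 32 differed at least 2-fold. The tumours of both lines did not overlap for 18.8% of genes, against 10% by chance. The count was 47 without radioresistant untreated replicate 1, 73 without replicate 3, 330 without radiosensitive untreated replicate 1, 66 without replicate 2 and 65 without replicate 3. Of 35 named genes that passed, 18 did so whichever array was left out, and calls lost numbered 15, 4 and 13 without radioresistant replicates 1, 2 and 3 and 0, 12 and 9 without the radiosensitive ones. The count was 83 with the wash run as a block, 44 within the first run alone, 27 with the station as a block and 33 when only the untreated arrays were fitted. It was 79 without the intensity trend and 297 with array weights. Both fits by wash run leave out radiosensitive untreated replicate 2, and without that array alone the count was 66. The block for the run also leaves out the radiosensitive arrays of 24 h. The median of the interferon-stimulated genes was 1.18 within the first wash run and 1.02 with the station as a block. It was 1.10 within the station that held arrays of both groups (3 against 1), where that of keratinocyte differentiation genes was -0.32.

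**Figure D2:**
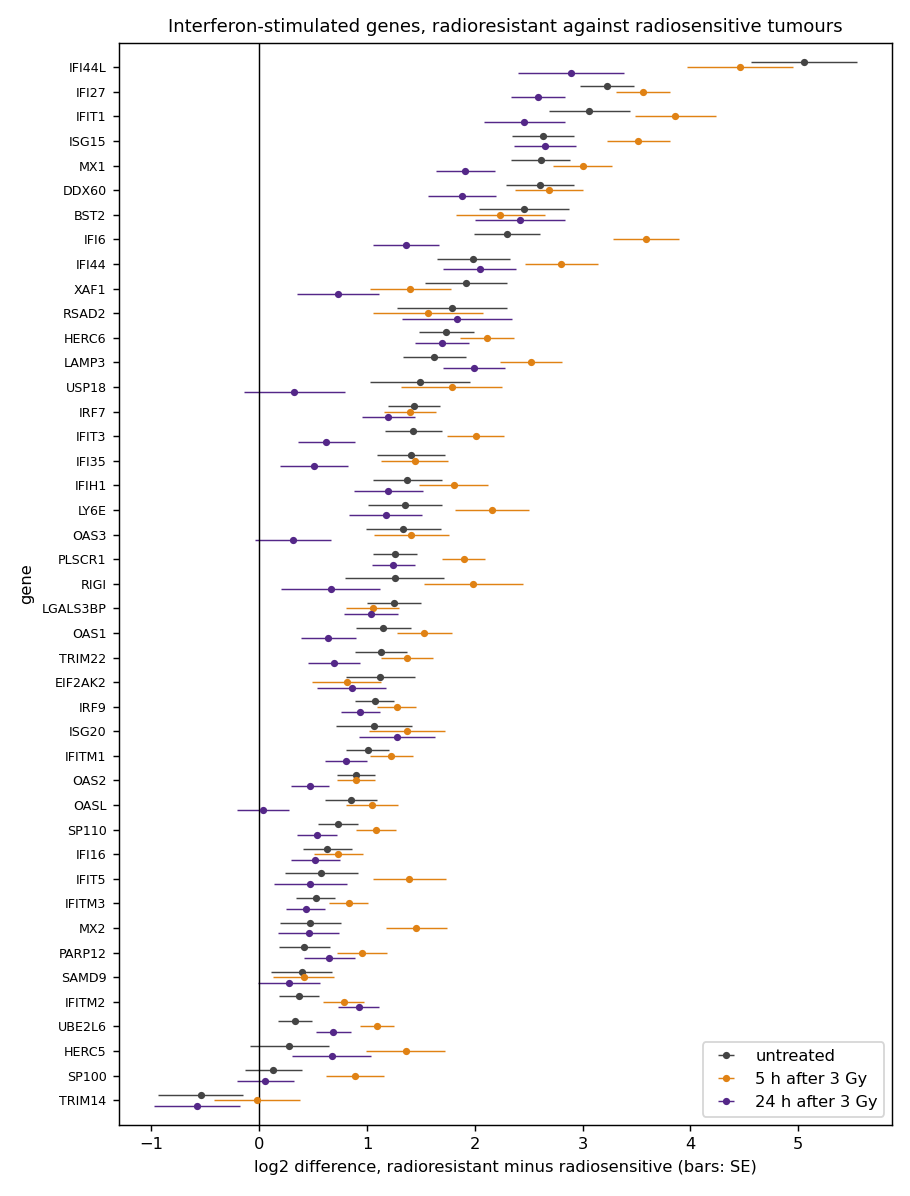
Log2 difference between radioresistant and radiosensitive tumours (horizontal axis) for each of 43 interferon-stimulated genes, with points for the model estimates and bars for their SE, in untreated tumours and 5 and 24 h after 3 Gy. In each condition 42 of the 43 estimates lie above 0, and IFI44L has the largest untreated difference.

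The next comparison asked which genes responded in radioresistant tumours 5 h after 3 Gy. No single gene passed with limma, and 291 genes had an unadjusted p under 0.05, against 418 expected by chance. Small shifts were shared across lists, with no single member called. Keratinocyte differentiation genes had a median log2 change of 0.29, and 26 of 32 lay above 0 (camera adjusted p = 3.59e-08; adjusted p = 0.117 with an estimated correlation). Their largest values were 1.13 for SPRR2B and 0.87 for SPRR3, both proline-rich proteins of the cornified envelope, and -1.16 for the keratin KRT4, none of which passed. Interferon-stimulated genes had a median of 0.32, with 41 of 43 above 0 (camera adjusted p = 1.37e-09; adjusted p = 0.185 with an estimated correlation), and ISG15 had the largest value, 0.82 (SE 0.29, adjusted p = 1).

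The 7-gene signature had a median of 0.52 at 5 h in radioresistant tumours, which is not independent evidence (camera adjusted p = 0.000293; adjusted p = 0.263 with an estimated correlation). IFIT1 had a log2 change of 0.52, MX1 0.54, IFIT3 0.51, IFI44 0.28 and OAS1 0.16. MHC class I genes had a median of 0.30 (camera adjusted p = 0.000129; adjusted p = 0.117 with an estimated correlation), with 0.48 for PSMB9 and 0.39 for HLA-C. All 12 NF-kappa-B inflammatory genes lay above 0 with a median of 0.21 (camera adjusted p = 0.0139; adjusted p = 0.117 with an estimated correlation), led by the cytokines IL1A at 0.55 and CXCL8 at 0.41. Immediate-early and heat-shock genes had a median of 0.29 (camera adjusted p = 0.00733; adjusted p = 0.263 with an estimated correlation), with 0.71 for IER3 and -0.57 for HSPH1. G2/M genes had a median of 0.15 (camera adjusted p = 0.00428; adjusted p = 0.371 with an estimated correlation), with 0.44 for TOP2A and 0.43 for CENPF. Glycolysis, with a median of 0.25, and oxidative phosphorylation, with 0.17, passed camera at adjusted p = 0.000971 and 0.000937, and both had adjusted p = 0.322 with an estimated correlation. CDKN1A had a log2 change of 0.09, GADD45A 0.06, FAS -0.04, CCNB1 0.19 and PLK1 0.07, and none passed.

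The smallest unadjusted p-values at 5 h in radioresistant tumours were those of DCTN1 (log2 -1.21), CEMIP2 (-1.50), PNPLA2 (1.17), DLK2 (0.98) and PIDD1 (1.32), all with adjusted p = 1. The tumours of both groups did not overlap for 9.32% of genes, against 10% by chance, and the count of called genes was 1 without radioresistant 5 h replicate 1. With quantile normalization MHC class I, immediate-early and heat-shock genes, glycolysis and oxidative phosphorylation no longer passed camera (adjusted p = 0.0882, 0.0962, 0.265 and 0.265). Without radioresistant untreated replicate 2, G2/M, NF-kappa-B, immediate-early and heat-shock genes, glycolysis and oxidative phosphorylation did not (0.153, 0.078, 0.073, 0.11 and 0.228). Without untreated replicate 3, G2/M did not (0.335). Without 5 h replicate 1, G2/M, immediate-early and heat-shock genes and oxidative phosphorylation did not (0.142, 0.0791 and 0.142), and without 5 h replicate 2, NF-kappa-B and immediate-early and heat-shock genes did not (0.0816 and 0.0773). With no filter the adjusted p was 0.0523 for NF-kappa-B, and with the station as a block it was 0.517 for G2/M, 0.111 for glycolysis and 0.722 for oxidative phosphorylation. Within the first wash run the median was 0.33 for keratinocyte differentiation and 0.29 for interferon-stimulated genes, and with the station as a block it was 0.25 and 0.31.

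At 24 h the same question was asked of radioresistant tumours. Keratinocyte differentiation genes had a median log2 change of 0.37, and 26 of 32 lay above 0 (camera adjusted p = 6.39e-12; adjusted p = 0.0804 with an estimated correlation). No single gene passed with limma over all genes, and 350 had an unadjusted p under 0.05; adjusted over the list alone, 5 keratinocyte differentiation genes were higher. SPRR2B had the largest value, 1.41 (SE 0.337, 6103 ± 2510 against 2250 ± 744, adjusted p = 0.938), LORICRIN had 1.23 and IVL, which codes for the envelope precursor involucrin, 0.61 (9784 ± 1460 against 6372 ± 763, adjusted p = 0.938).

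Further lists passed camera at 24 h in radioresistant tumours, and none held with an estimated correlation. p53 targets had a median of 0.20 (camera adjusted p = 0.015; adjusted p = 0.338 with an estimated correlation), with 0.89 for TIGAR, a regulator of glycolysis, 0.54 for ZMAT3, 0.48 for DDB2, 0.20 for CDKN1A, 0.15 for GADD45A and -0.04 for FAS. Hypoxia genes had a median of 0.26 (camera adjusted p = 0.00358; adjusted p = 0.533 with an estimated correlation), with 0.83 for PFKFB3 and 0.73 for EGLN3. Glycolysis had a median of 0.29 and oxidative phosphorylation 0.13 (camera adjusted p = 0.00196 and 0.00455; adjusted p = 0.533 for both with an estimated correlation), with 0.88 for ALDOC and 0.55 for LDHA. Interferon-stimulated genes had a median of -0.19 (camera adjusted p = 0.015; adjusted p = 0.611 with an estimated correlation), with -0.79 for IFI44L and -0.75 for XAF1. ISG15 had a log2 change of -0.06, MX1 -0.17, IFIT1 -0.37, IFIT3 -0.34, IFI44 -0.42, OAS1 -0.21, CCNB1 0.21 and PLK1 -0.05.

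Other small unadjusted p-values at 24 h in radioresistant tumours were those of AKAP13 (log2 -1.36), MYOZ1 (-1.24) and DNM1 (-0.91), with adjusted p = 0.938, and the tumours did not overlap for 11% of genes, against 10% by chance. The median of the interferon-stimulated genes was 0.08 without radioresistant 24 h replicate 1, whose mean of that list was 9.86 against 10.65 and 10.53, and the list did not pass without untreated replicate 1 (adjusted p = 0.34) or with the station as a block (0.58). The p53 list did not pass without untreated replicates 2 or 3 or 24 h replicate 1 (adjusted p = 0.0612, 0.066 and 0.393). Hypoxia and glycolysis did not without untreated replicate 2 (0.0787 and 0.0691) or 24 h replicate 1 (both 0.455), nor oxidative phosphorylation without untreated replicate 2 (0.317). With the station as a block the adjusted p was 0.425 for p53 targets, hypoxia and glycolysis and 0.702 for oxidative phosphorylation, and with the wash run as a block 0.127 for hypoxia. Quantile normalization ended the calls of p53 targets, glycolysis and oxidative phosphorylation (adjusted p = 0.0579, 0.293 and 0.511). The count of called genes was 40 with array weights and 1 without both arrays that stood apart. The keratinocyte median was 0.54 with the wash run and 0.30 with the station as a block. All untreated radioresistant arrays were in the first run on station 1, and all of 24 h in the second on station 2. Neither block separates run or station from time here, since both rest on arrays of other groups.

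In radiosensitive tumours 5 h after 3 Gy, keratinocyte differentiation genes were the only list past camera. Their median log2 change was 0.33, and 27 of 32 lay above 0 (camera adjusted p = 8.39e-08; adjusted p = 0.289 with an estimated correlation). No single gene passed with limma over all genes, and 630 had an unadjusted p under 0.05; adjusted over the list alone, 1 keratinocyte gene was higher. That gene was TGM1, the transglutaminase that crosslinks the cornified envelope, with log2 1.48 (SE 0.316, 679.4 ± 204 against 227.9 ± 74.8, adjusted p = 0.376 over all genes), followed by LORICRIN at 1.24 and SPRR3 at 1.16.

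Interferon-stimulated genes had a median of -0.01 at 5 h in radiosensitive tumours (camera adjusted p = 0.477), the p53 list 0.07 (0.672) and G2/M genes -0.15 (0.0519). CDKN1A had a log2 change of 0.25 (adjusted p = 0.683), GADD45A 0.23, FAS -0.04, CCNB1 -0.34, PLK1 0.53, ISG15 -0.07, MX1 0.15, IFIT1 -0.27, IFIT3 -0.07, IFI44 -0.54 and OAS1 -0.22. RHOC had the smallest unadjusted p, with log2 1.28 (adjusted p = 0.313), then TGM1, AP2S1 (0.64), KIF1C (1.72) and the deacetylase HDAC9 (-1.63), with adjusted p = 0.376. The tumours did not overlap for 12.4% of genes, against 10% by chance, and the count of called genes was 3 without radiosensitive untreated replicate 1. Without untreated replicate 2, the array with the high 3' to 5' ratio, and 24 h replicate 2, the keratinocyte median was 0.32, with the wash run as a block it was 0.42 and with the station as a block 0.36. No usable wash run held both untreated and 5 h radiosensitive arrays, so the block for the run rests on radioresistant tumours.

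At 24 h in radiosensitive tumours keratinocyte differentiation genes had a median log2 change of 0.42, and 24 of 32 lay above 0 (camera adjusted p = 5.23e-05; adjusted p = 0.418 with an estimated correlation). None passed over all genes, and 9 were higher when adjusted over the list alone. SPRR3 had log2 1.67, SPRR2B 1.39, TGM1 1.37 and CRCT1 1.03. Markers of other cell types had medians of 0.56 for skeletal muscle and fat (camera adjusted p = 0.11) and 0.42 for endothelium (5 of 6 above 0, camera adjusted p = 0.316), and neither passed. IVL had 0.84 (SE 0.154, 12360 ± 522 against 6911 ± 966, adjusted p = 0.114). The 1 gene that passed was NPIPA1, a member of a family of nuclear pore interacting proteins, which fell 2.09-fold (log2 -1.07, SE 0.156, 2339 ± 364 against 4908 ± 579, limma adjusted p = 0.0213).

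NF-kappa-B inflammatory genes had a median of 0.44 at 24 h in radiosensitive tumours, with 1.03 for the chemokine CXCL1, 0.84 for CXCL8 and 0.81 for IL1A, and did not pass camera (adjusted p = 0.0674). The list passed fry, which asks whether its genes move on balance one way (fry adjusted p = 0.0131). No other list passed fry in a response to irradiation. CDKN1A had a log2 change of 0.37 (SE 0.128, unadjusted p = 0.00882, adjusted p = 0.244), PLK1 0.95 (adjusted p = 0.216), GADD45A -0.55, FAS 0.28 and CCNB1 0.05. The p53 list had a median of 0.02 and interferon-stimulated genes 0.10, and neither passed; MX1 had 0.53, IFIT3 0.47, OAS1 0.30, IFIT1 0.23, ISG15 -0.08 and IFI44 -0.48. Other small unadjusted p-values were those of the protease ST14 (log2 1.04), HABP4 (1.62) and the growth factor receptor FGFR2 (-1.80), with adjusted p = 0.127.

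In this comparison of radiosensitive tumours at 24 h, 1115 genes had an unadjusted p under 0.05, and tumours did not overlap for 15% of genes, against 10% by chance. The number of called genes was 64 without radiosensitive untreated replicate 1, 19 without 24 h replicate 1 and 0 without untreated replicate 2, untreated replicate 3 or 24 h replicate 3, which ended the call of NPIPA1. It was 0 with quantile normalization, without the intensity trend or with only the groups compared, and 13 with the station as a block. The arrays that stood apart, untreated replicate 2 and 24 h replicate 2, are both in it, and without them the keratinocyte median was 0.55. With the station as a block it was 0.23 (camera adjusted p = 0.0816). That fit leaves out 24 h replicate 1, and without that array alone the median was 0.27 (0.0457). The wash run could not be separated from this comparison.

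**Figure D3:**
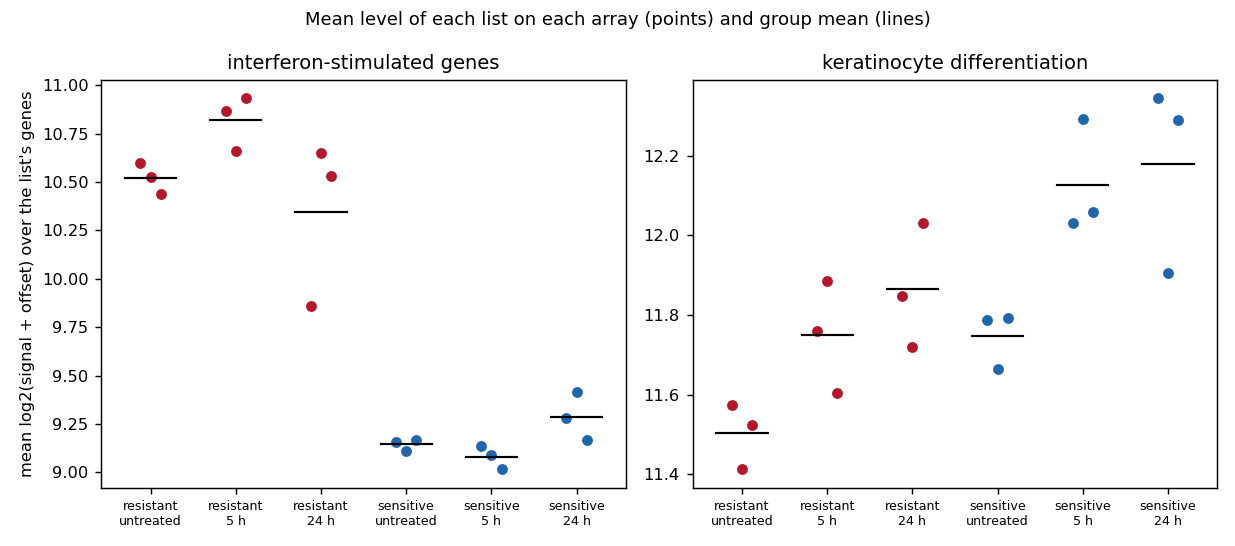
Mean log2(signal + 24.7) over the measured genes of a list (vertical axis) on each array (points) with the group mean (lines), for 43 interferon-stimulated genes and 32 keratinocyte differentiation genes in the 6 groups. Interferon-stimulated genes separate the lines, with radioresistant 24 h replicate 1 at 9.86 the lowest radioresistant array, and keratinocyte differentiation genes lie higher after 3 Gy than in untreated tumours of the same line.

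The difference of responses asked which genes responded otherwise in radioresistant than in radiosensitive tumours. At 5 h the response of the interferon-stimulated genes was higher in radioresistant tumours by a median of 0.35, and 36 of 43 lay above 0 (camera adjusted p = 5.89e-07; adjusted p = 0.666 with an estimated correlation). IFI6 had the largest value, 1.29, then HERC5 at 1.08 and MX2 at 0.98, and none passed. The 7-gene signature had a median of 0.69, which is not independent evidence (camera adjusted p = 0.00126; adjusted p = 0.666 with an estimated correlation), with 0.88 for ISG15, 0.82 for IFI44, 0.80 for IFIT1, 0.58 for IFIT3, 0.39 for MX1 and 0.38 for OAS1. G2/M genes had a median of 0.31 (camera adjusted p = 6.44e-05; adjusted p = 0.666 with an estimated correlation), with 1.14 for CENPF and 0.74 for FOXM1.

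No gene passed the difference of responses at 5 h with limma, and 280 had an unadjusted p under 0.05. The smallest were those of PLCB3 (log2 2.54), LMTK2 (-2.80), PIMREG (1.41), HSPH1 (-1.25) and DDX6 (2.63), with adjusted p = 0.998. CDKN1A had -0.16, GADD45A -0.17, FAS 0.00, CCNB1 0.52 and PLK1 -0.47, and the keratinocyte list's difference was -0.09 (camera adjusted p = 0.682). The G2/M median was 0.16 with the wash run and 0.12 with the station as a block (camera adjusted p = 0.396 and 0.345), while that of the interferon-stimulated genes was 0.51 and 0.54.

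At 24 h the response of the oxidative phosphorylation genes was higher in radioresistant tumours by a median of 0.29 (camera adjusted p = 0.02; adjusted p = 0.792 with an estimated correlation), with 0.80 for COX7B and 0.80 for ATP5F1A. Interferon-stimulated genes had a median of -0.18, with 9 of 43 above 0 (camera adjusted p = 0.0346; adjusted p = 0.792 with an estimated correlation), and IFI44L had the largest value, -2.16 (adjusted p = 0.452). The smallest unadjusted p-values were those of NOP2, a ribosomal RNA methyltransferase (log2 1.29), TFRC, the transferrin receptor (1.15), TUBB6 (1.61), PNPLA2 (1.78) and ANP32B (0.93), with adjusted p = 0.452.

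No gene passed the difference of responses at 24 h with limma, and 762 had an unadjusted p under 0.05. CDKN1A had -0.17, GADD45A 0.70, FAS -0.32, CCNB1 0.16, PLK1 -1.003, ISG15 0.02, MX1 -0.70, IFIT1 -0.61, IFIT3 -0.81, IFI44 0.06 and OAS1 -0.51, and the keratinocyte list's difference was -0.07 (camera adjusted p = 0.882). The interferon median was 0.01 without radioresistant 24 h replicate 1. Its call also ended without radioresistant untreated replicate 1, radiosensitive untreated replicates 1 or 3 and radiosensitive 24 h replicates 1 or 2 (adjusted p = 0.167, 0.0866, 0.0545, 0.0862 and 0.195). So it did with no filter (0.0734), without both arrays that stood apart (0.254) and with the station as a block (0.27). The oxidative phosphorylation median was -0.02 with quantile normalization. Its call ended without radioresistant untreated replicate 2, radiosensitive untreated replicate 3 or radiosensitive 24 h replicate 2 (adjusted p = 0.0926, 0.0616 and 0.195), without both arrays that stood apart (0.468) and with the station as a block (0.27). The count of called genes was 2 without radiosensitive untreated replicate 1.

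Among irradiated tumours at 5 h, the comparison of the lines again had interferon-stimulated genes as its largest group. IFIT1 was 14.5-fold higher in radioresistant tumours (4735 ± 1820 against 310.8 ± 150, limma adjusted p = 5.07e-06), IFI27 11.8-fold (17700 ± 3830 against 1471 ± 272, adjusted p = 1.89e-07) and ISG15 11.5-fold (adjusted p = 8.67e-07). IFI44L was 22.1-fold higher, IFI6 12-fold, MX1 8.02-fold, IFI44 6.98-fold and DDX60 6.46-fold. KRT76 was 12.9-fold lower (57.87 ± 20.5 against 1040 ± 259, adjusted p = 1.75e-06), PDLIM4 7.91-fold and STK26 7.59-fold. KRT4, a keratin of stratified mucosa, was 5.65-fold lower (3210 ± 626 against 18050 ± 477, adjusted p = 0.0188), a call lost whichever of the 6 arrays was left out (adjusted p = 0.0517 to 0.0796).

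At 5 h 31 of 43 interferon-stimulated genes were higher and none lower, or 41 adjusted over the list alone, with a median log2 difference of 1.41 (camera adjusted p = 1.14e-68; adjusted p = 0.000639 with an estimated correlation). The 7-gene signature had 6 of 6 higher, and 6 adjusted over the list alone, with a median of 2.90, which is not independent evidence (camera adjusted p = 1.69e-22; adjusted p = 0.00422 with an estimated correlation). OAS1 was 2.89-fold higher (adjusted p = 0.00239) and IFIT3 4.03-fold (adjusted p = 0.000213). Of 16 MHC class I genes 5 were higher and none lower, or 10 higher and 1 lower adjusted over the list alone, with a median of 0.69 (camera adjusted p = 3.7e-09; adjusted p = 0.0116 with an estimated correlation), among them HLA-B 2.31-fold, PSMB9 2.02-fold and HLA-C 1.79-fold.

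Keratinocyte differentiation genes were lower at 5 h with a median of -0.45, with 4 lower and 2 higher, or 12 lower and 4 higher adjusted over the list alone (camera adjusted p = 0.000126; adjusted p = 0.232 with an estimated correlation). LORICRIN, the main protein of the cornified envelope, was 3.99-fold lower (adjusted p = 0.0345; 0.0629 to 0.174 over the arrays left out, so lost each time). SERPINB4 was 3.42-fold and LCN2 2.78-fold higher. G2/M genes had a median of 0.39, with 1 higher, or 1 adjusted over the list alone (camera adjusted p = 1.05e-05; adjusted p = 0.232 with an estimated correlation), which was the securin PTTG1, 1.86-fold (adjusted p = 0.0345). That call was lost whichever of the 6 arrays was left out (0.0723 to 0.162). Mesenchymal and invasion genes had a median of 0.26, with 1 higher, or 2 adjusted over the list alone (camera adjusted p = 0.0241; adjusted p = 0.232 with an estimated correlation). The 1 was INHBA, an activin subunit, 2.09-fold (adjusted p = 0.0363), again lost with each array left out (0.0839 to 0.137). This list's call also ended without radioresistant 5 h replicate 2 (adjusted p = 0.0744), without radiosensitive 5 h replicate 2 (0.122) and with the wash run as a block (0.0696). Some members of lists that did not pass at 5 h were called. AKR1C3 of the NRF2 list was 3.07-fold higher, WARS1 of the interferon-gamma list 2.39-fold, CYC1 of oxidative phosphorylation 2.01-fold and ERO1A of the hypoxia list 3.15-fold, while the fibroblast marker DCN was 2.57-fold lower. Of the 6 arrays left out in turn, CYC1 kept its call with 2 and ERO1A with 1. CDKN1A had a log2 difference of -0.22, GADD45A -0.26, FAS 0.34, CCNB1 0.54 and PLK1 -0.14, and none passed. Other large falls were SH3YL1, 5.65-fold, the lysosomal sulfatase SGSH, 5.57-fold, RAP2C, 5.15-fold, and ASAP3, 4.48-fold (adjusted p = 0.0241). ASAP3 kept its call with 2 of the 6 arrays left out in turn.

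In all, limma called 121 genes between the lines at 5 h, 76 higher and 45 lower, of which 57 and 25 differed at least 2-fold, and tumours did not overlap for 22.4% of genes, against 10% by chance. The count was 58 without radioresistant 5 h replicate 1, 76 without replicate 2, 71 without radiosensitive 5 h replicate 2 and 72 without replicate 3. Of 32 named genes that passed, 21 did so whichever array was left out, and calls lost numbered 9, 9 and 6 without radioresistant replicates 1, 2 and 3 and 6, 8 and 8 without the radiosensitive ones. The count was 44 with the wash run as a block, 61 with the station as a block, 253 with array weights, 160 when only the 5 h arrays were fitted and 221 without both arrays that stood apart. It was 23 within the second wash run (1 array against 3), where the medians were 1.62 for interferon-stimulated and -0.49 for keratinocyte differentiation genes. Those arrays were also the ones on a shared station.

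At 24 h interferon-stimulated genes were again higher in radioresistant tumours. IFI27 was 6-fold higher (15280 ± 5340 against 2498 ± 793, limma adjusted p = 2.65e-05), ISG15 6.28-fold (adjusted p = 5.5e-05), IFIT1 5.49-fold (adjusted p = 0.0016), BST2 5.35-fold and MX1 3.76-fold (adjusted p = 0.00113). IFI44L was 7.43-fold and IFI44 4.13-fold higher, while OAS1 (log2 0.64, adjusted p = 0.172) and IFIT3 (0.62, adjusted p = 0.201) did not pass. PDLIM4 was 10.9-fold lower, KRT76 10.1-fold (56.07 ± 16.6 against 781.3 ± 102, adjusted p = 2.65e-05) and STK26 5.46-fold (adjusted p = 5.5e-05).

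At 24 h 18 of 43 interferon-stimulated genes were higher and none lower, or 31 adjusted over the list alone, with a median of 0.81 (camera adjusted p = 1.91e-25; adjusted p = 0.0403 with an estimated correlation). The 7-gene signature had 4 of 6 higher, or 6 adjusted over the list alone, with a median of 1.98, which is not independent evidence (camera adjusted p = 1.6e-09; adjusted p = 0.0645 with an estimated correlation). Of 16 MHC class I genes 6 were higher, or 11 adjusted over the list alone, with a median of 0.69 (camera adjusted p = 2.61e-07; adjusted p = 0.0403 with an estimated correlation), among them HLA-B 2.54-fold, HLA-G 2.03-fold, HLA-C 1.91-fold and PSMB9 1.75-fold. HLA-G kept its call with 1 of the 6 arrays left out in turn, while HLA-B, HLA-C and PSMB9 kept theirs with all 6.

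Keratinocyte differentiation genes had a median of -0.21 at 24 h, with 3 lower and 2 higher, or 10 lower and 4 higher adjusted over the list alone (camera adjusted p = 0.0254; adjusted p = 0.48 with an estimated correlation). KLK5, a kallikrein of the epidermis, was 2.68-fold lower and the keratin KRT13 2.14-fold lower, while SERPINB4 was 2.74-fold and SERPINB3 2.1-fold higher. Both serpins kept their calls with 2 of the 6 arrays left out in turn, and KLK5 and KRT13 with 3. Oxidative phosphorylation genes had a median of 0.33, with 2 higher, or 7 adjusted over the list alone (camera adjusted p = 0.000113; adjusted p = 0.408 with an estimated correlation). They were CYC1, 1.81-fold, and COX5A, 1.64-fold, calls each kept with 1 of the 6 arrays left out in turn. Glycolysis had a median of 0.39, with 1 higher, or 1 adjusted over the list alone, the lactate dehydrogenase LDHB, 1.92-fold, and hypoxia genes 0.25 with none passing, or 0 adjusted over the list alone (camera adjusted p = 0.00802 and 0.0184; adjusted p = 0.48 for both with an estimated correlation). Of 19 p53 targets 2 were higher, or 3 adjusted over the list alone, and the list did not pass (median 0.04, camera adjusted p = 0.229). They were TNFRSF10B, a death receptor, 1.95-fold (adjusted p = 0.0396), and RPS27L, 1.85-fold (adjusted p = 0.048), calls kept with 2 and 1 of the 6 arrays left out in turn. CDKN1A had a log2 difference of -0.24, GADD45A 0.62, FAS 0.02, CCNB1 0.18 and PLK1 -0.68, and these did not pass. Of the NRF2 list, which did not pass, 3 were higher, among them AKR1C3, 2.68-fold, and AKR1C2, 1.94-fold, and 2 lower, ALDH3A1, 2.95-fold, and AKR1B10, 1.93-fold. TGFBI of the mesenchymal list was 2.57-fold higher and CDC45 of the G1/S list 3.82-fold. The call of CDC45 was lost whichever of the 6 arrays was left out (adjusted p = 0.0521 to 0.144), and TGFBI and AKR1B10 kept theirs with 2 of the 6. The fibroblast marker DCN was 2.1-fold lower. Outside the lists ROBO1, an axon guidance receptor, was 4.49-fold higher, the cadherin CDH19 4.68-fold and HSD17B1 4.47-fold, and KIR3DX1 was 4.67-fold lower, FYB1 4.58-fold, CTAGE11P 4.08-fold, the complement component C6 4.08-fold and CRISPLD2 3.78-fold. ROBO1 kept its call whichever of the 6 arrays was left out. CDH19, KIR3DX1 and CRISPLD2 kept theirs with 2 of the 6, and HSD17B1, FYB1, CTAGE11P and C6 with 1.

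The line difference at 24 h had medians below 0 for markers of other cell types, and no list of them passed. They were -0.69 for skeletal muscle and fat (camera adjusted p = 0.0978; 3 lower and 1 higher adjusted over the list alone) and -0.65 for endothelium (6 of 6 below 0, adjusted p = 0.113). Macrophages and leukocytes had -0.41 (adjusted p = 0.231) and fibroblasts -0.35 (adjusted p = 0.598).

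In all, limma called 180 genes between the lines at 24 h, 119 higher and 61 lower, of which 63 and 40 differed at least 2-fold, and tumours did not overlap for 26.7% of genes, against 10% by chance. The count was 82, 50 and 95 without radioresistant 24 h replicates 1, 2 and 3, and 411, 52 and 83 without radiosensitive 24 h replicates 1, 2 and 3. Of 38 named genes that passed, 16 did so whichever array was left out, and calls lost numbered 15, 21 and 16, and 3, 20 and 17, in the same order. The count was 17 when only the 24 h arrays were fitted, 64 without both arrays that stood apart, 279 with the station as a block, 762 with array weights, 99 without the intensity trend and 116 with no filter. The station block leaves out radiosensitive 24 h replicate 1, and without that array alone the count was 411. The interferon median was 0.92 within the station that held both lines (3 arrays against 2), and the keratinocyte median there -0.24. The wash run could not be separated from the line. The calls of hypoxia, glycolysis and oxidative phosphorylation ended with quantile normalization (adjusted p = 0.18, 0.407 and 0.263). Those of hypoxia and glycolysis without radioresistant 24 h replicate 1 (0.377 and 0.207) or radiosensitive 24 h replicate 2 (0.135 and 0.0644) or both arrays that stood apart (0.157 and 0.0598), and that of hypoxia without radiosensitive replicate 3 (0.157). That of keratinocyte differentiation ended without radioresistant replicate 2 (0.151), without radiosensitive replicates 1 or 3 (0.283 and 0.157) and with the station as a block (0.279).

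The genes called between the lines were shared across conditions. Of 81 genes higher in untreated radioresistant tumours, 45 were also higher at 5 h and 39 at 24 h, against 0.736 and 1.15 expected of independent sets, and of 66 lower genes 23 and 19 were also lower, against 0.355 and 0.481. None was called in opposite directions. The comparisons used the same lines and shared 1 estimate of each gene's spread, which can by itself raise the overlap above that of independent sets. In all 3 conditions 31 genes were higher, 16 of them interferon-stimulated, and 16 were lower, among them KRT76, PDLIM4, STK26 and RAP2C.

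**Figure D4:**
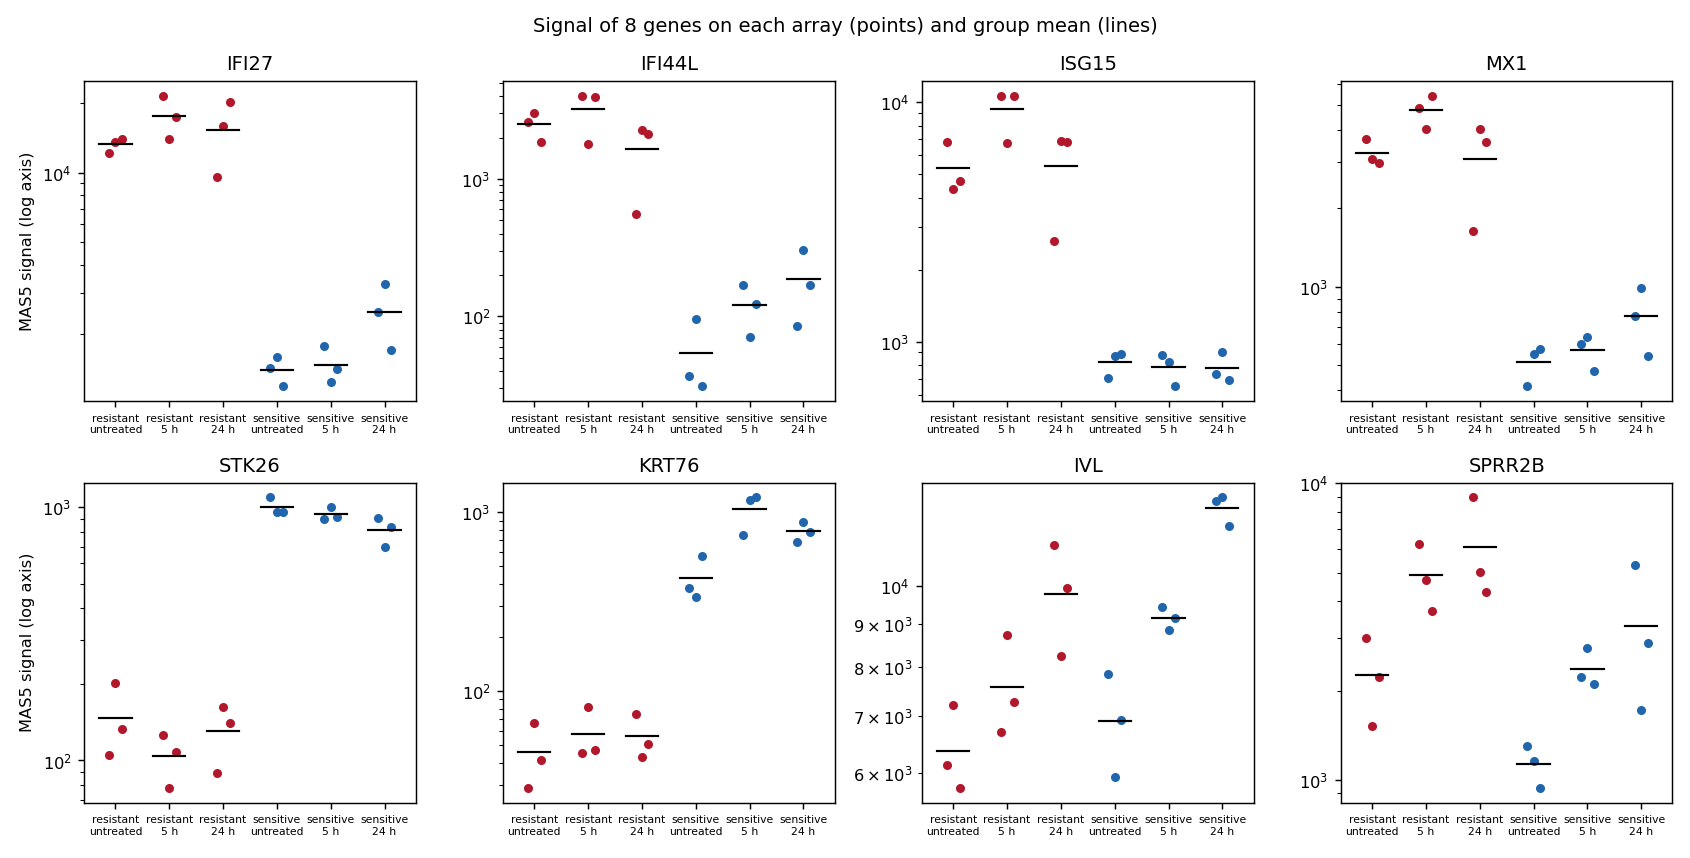
MAS5 signal (vertical log axis) of 8 genes on each array (points) with the group mean (lines), in radioresistant and radiosensitive tumours that were untreated or 5 or 24 h after 3 Gy. IFI27 has a mean of 13280 in untreated radioresistant and 1404 in untreated radiosensitive tumours, STK26 has 147 and 1003, and IVL in radiosensitive tumours has 6911 untreated and 12360 at 24 h.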

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

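Tests of RNA quality, wash run, stroma and signal range were set before their results were seen, while the counts over other splits of the samples, the exact permutations of list means and the fluidics station block were chosen after the results were seen. The difference between the lines' responses passed camera for a few lists, which marked them for a closer look, and each lost its call with an estimated correlation. At 5 h the median difference of responses was 0.353 for interferon-stimulated genes (camera adjusted p = 5.89e-07; adjusted p = 0.666 with an estimated correlation), 0.687 for the 7-gene interferon-related signature (0.00126; 0.666), which shares its genes with that list, and 0.306 for G2/M and mitosis (6.44e-05; 0.666). At 24 h it was -0.179 for interferon-stimulated genes (0.0346; 0.792) and 0.0123 without radioresistant 24 h replicate 1. For oxidative phosphorylation it was 0.288 (0.02; 0.792) at 24 h, and -0.0241 with quantile normalization.

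The first pattern weighed is the higher level of interferon-stimulated genes in untreated radioresistant tumours, a median log2 difference of 1.26. Without radiosensitive untreated replicate 2, the array with the high 3' to 5' ratio, the median was 1.18, a ratio of 0.936 (SD 0.073 over list members), which argues against that array as its cause, and the first wash run alone holds the same arrays and gives the same 0.936, which argues against the run. The ACTB ratios of the other radiosensitive untreated arrays, 3.62 and 5.43, were also above the radioresistant ones, 2.76 to 3.04. This milder difference in RNA quality was not tested. Signals of bioB, a control added to each array, also differed by line untreated, 438.6 to 685.1 in radioresistant and 844.8 to 2189 in radiosensitive tumours. At 5 h they were 498.7 to 1048 and 1541 to 1890, and at 24 h they overlapped (619.3 to 928.5 and 546.9 to 1027). The part of this difference was not tested either. At 24 h the ACTB ratio was not higher in radiosensitive tumours (3.01 to 3.41 against 3.33 to 4.19). The list's mean at 24 h was 10.35 in radioresistant and 9.287 in radiosensitive tumours. The highest median of the fibroblast, endothelial and leukocyte markers was -0.126, which argues against more human stroma or leukocytes, although host stroma is murine and only 9, 6 and 7 of these markers were measured. An exact permutation of the list's mean within each condition gave a line difference of 1.39 with p = 0.00025, the smallest that 8000 arrangements can give (adjusted p = 0.00131 over the lists). This permutation takes neither the wash run nor the fluidics station into account. A stable difference of the line itself may account for the pattern, as a hypothesis, but a difference in culture history or in host response was not tested, and the line and its tumours cannot be separated in this design.

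The second pattern is the higher level of keratinocyte differentiation genes after 3 Gy in both lines. With an estimated correlation its camera calls were lost in radioresistant (adjusted p = 0.117 at 5 h and 0.0804 at 24 h) and radiosensitive tumours (0.289 and 0.418). The array with the high 3' to 5' ratio is among the untreated radiosensitive tumours, and without it the median at 24 h was 0.337 instead of 0.42, a ratio of 0.803 (SD 0.42), so that its part there cannot be told apart from the response; the radioresistant comparisons do not use it. Within the first wash run the radioresistant median at 5 h was 0.326 against 0.293 over all arrays, a ratio of 1.11 (SD 0.22), which argues against the wash run for that comparison, while in radiosensitive tumours at 24 h the run cannot be separated from the time. In radioresistant tumours at 24 h and radiosensitive tumours at 5 h, no usable run held both untreated and irradiated arrays either. In the first run the radioresistant untreated arrays were all on station 1 and those of 5 h all on station 2. The comparison within that run therefore does not separate the station from the time. With the fluidics station as a block the radiosensitive median at 24 h was 0.229 and the call at the preset correlation ended too (adjusted p = 0.0816). The same arrays without the block gave 0.267, a ratio of 0.857 (SD 0.76), so the part of the station cannot be told apart from that of the array left out. With both lines together an exact permutation within each line gave a mean difference of 0.355 between irradiated and untreated tumours (p = 0.000425 over 7056 arrangements, adjusted p = 0.00892), and no other list passed. Untreated and irradiated tumours were mostly washed in different runs, which this permutation does not take into account. A response to irradiation may account for the pattern, and the wash run outside the comparison above, the fluidics station, the day of collection and the age of the tumours stay open.

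The third pattern is that more genes had an unadjusted p under 0.05 at 24 h in radiosensitive than in radioresistant tumours, 1115 against 350. Without radiosensitive 24 h replicate 2, which had the low signal range, the count was 735, a ratio of 0.659. Leaving out any other array of the comparison gave between 879 and 1466, so the count was lowest without that array. Without untreated replicate 1, 24 h replicate 1 or 24 h replicate 3 it rose to 1326, 1466 and 1167, so fewer arrays alone did not lower it. The ratio lay between the limits set before, 0.5 and 0.8, so the size of that array's part in the larger count stays open. The direct test of the difference called 0 genes with limma (762 with an unadjusted p under 0.05), so a larger response of radiosensitive tumours is not shown.

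Other splits of the same samples were counted for each comparison. For 3 tumours against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 147 and 1 for the lines untreated, 121 and 0 at 5 h and 180 and 0 at 24 h, each with 1 of 10 splits as large. For the responses they were 0 and 0 in radioresistant tumours at 5 h and 0 and 1 at 24 h, 0 and 2 in radiosensitive tumours at 5 h, each with 10 of 10 splits as large because every split meets a count of 0, and 1 and 2 in radiosensitive tumours at 24 h, with 4 of 10. For the differences of responses, the count found was also 0, with a highest of 2 at both times. All 100 splits drawn meet it, so counts against 0 say nothing about chance.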

How the results depend on the processing

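The blocks for wash run and fluidics station, the first wash run alone and the fit without both arrays that stood apart were chosen after seeing the data. Counts are given in the order untreated, 5 h, 24 h for the difference between the lines, whose counts were 147, 121 and 180. They stayed within 1.5 times these with quantile normalization, no offset, 4 times the offset, the filter at the 60th percentile, the tumour number as a block and the mean of a gene's probe sets. At 24 h the count was 116 with no filter, where more probe sets are adjusted for. It was 33 and 17 untreated and at 24 h with only the groups compared, against 160 at 5 h, and 79 and 99 without the intensity trend. Array weights gave 297, 253 and 762, and 40 instead of 0 in radioresistant tumours at 24 h. Without both arrays that stood apart it was 221 at 5 h and 64 at 24 h, and 1 instead of 0 in radioresistant tumours at 24 h. With the wash run as a block it was 83 untreated and 44 at 5 h, and the 24 h comparisons of radiosensitive tumours could not be fitted. The first wash run alone gave 44 untreated. Both fits leave out radiosensitive untreated replicate 2, and without that array alone the untreated count was 66. With the station as a block it was 27, 61 and 279, and 13 instead of 1 in radiosensitive tumours at 24 h, where quantile normalization, no intensity trend and only the groups compared gave 0. The station block leaves out radiosensitive 24 h replicate 1. Without this array alone the line count at 24 h was 411 and that of the radiosensitive response at 24 h was 19. Leaving out each array gave 47 to 330 untreated, 58 to 89 at 5 h and 50 to 411 at 24 h. For the responses it gave 0 to 1 in radioresistant tumours at 5 h, 0 to 3 in radiosensitive tumours at 5 h, 0 to 64 in radiosensitive tumours at 24 h and 0 to 2 for the difference of responses at 24 h. Among the 39 list calls, medians turned over 0 in 3 cases: oxidative phosphorylation in the difference of responses at 24 h was -0.0241 with quantile normalization, and interferon-stimulated genes at 24 h ranged from -0.347 to 0.0811 in radioresistant tumours and from -0.341 to 0.0123 in the difference of responses over the arrays left out, the highest without radioresistant 24 h replicate 1. Except where stated, the cause was not tested.

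Tumours of equal number in different groups had a median correlation of -0.000101 in their deviations from the group means. Of 45 such pairs 8 were over 0.1, with a highest of 0.44, against 6 of 90 pairs of different numbers, with a highest of 0.207, and 10 of 18 arrays correlated best with one of their own number. These values do not settle whether equal numbers mark pairs. The labels state no pairing, so the numbers were not read as pairs, and the tumour number was tried as a block.

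Of 39 list calls, 8 kept their side of the threshold with an estimated correlation and 31 lost it, and all 39 kept it with the tumour number as a block. The 106 calls of named genes gave 1990 values under the alternatives, of which 1591 passed, 399 did not and 0 reversed. Quantile normalization moved the median of all genes by less than 0.1 in each of the 9 comparisons. Genes with signals near the offset of 24.7, such as IFI44L and KRT76, have folds that depend on the offset. A block for chip lot or scan day was not run.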

Other observations

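The averaged comparisons, the splits of the samples, the exact permutations, the first wash run alone and the test of genes flanking STK26 and RAP2C were chosen after the results were seen. The camera tests, the estimated correlation, quantile normalization, the fit without the intensity trend and leaving out each array were planned. With the 3 conditions averaged, so that 9 arrays of each line were compared in the same limma model, 1127 genes differed between the lines, 611 higher and 516 lower in radioresistant tumours, of which 77 and 56 differed at least 2-fold. Of 100 splits of the samples within conditions 1 gave as many, the real one, and the highest of the others gave 1. That share is under 0.05 and argues against a chance division of the tumours, in a test chosen after the results were seen. The splits take neither the wash run nor the fluidics station into account. The averaged count was not tried with a block or with an array left out. Exact permutations of list means put the higher interferon-stimulated genes (1.39) and MHC class I genes (0.549) and the lower endothelial markers (-0.47, 6 genes) at adjusted p = 0.00131, lower keratinocyte differentiation genes (-0.312) at 0.00315, higher mesenchymal and invasion genes (0.195) at 0.0201, and higher hypoxia (0.267) and oxidative phosphorylation genes (0.172) at 0.0454. These permutations take neither the wash run nor the fluidics station into account, and at 24 h no usable run held both lines. The mean of the oxidative phosphorylation list in radioresistant against radiosensitive tumours was 11.68 against 11.63 untreated. It was 11.84 against 11.7 at 5 h and 11.84 against 11.52 at 24 h. Within the first wash run the untreated median of the mesenchymal list was -0.0414, against 0.205 over all arrays. The camera calls of hypoxia and oxidative phosphorylation at 24 h ended with quantile normalization (adjusted p = 0.18 and 0.263) and with an estimated correlation (0.48 and 0.408). For keratinocyte differentiation genes the camera call was lost with an estimated correlation in each condition (0.59 untreated, 0.232 at 5 h and 0.48 at 24 h) and with quantile normalization untreated (0.2). The endothelial list did not pass camera in any condition (0.232, 0.338 and 0.113). Its markers were read by human probe sets, while host endothelium is murine.

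With both lines averaged, IVL was higher 24 h after 3 Gy (log2 0.73, adjusted p = 0.0236) and NPIPA1 lower, the 2 genes that passed in limma. Of 100 splits, 2 gave as many, the real one included, a share under 0.05. Another split reached the same count of 2, and the test was among those chosen after the results were seen. Chance is therefore not excluded for the count or for either gene. Untreated and 24 h tumours shared no usable wash run, which the splits do not take into account. In radiosensitive tumours alone NPIPA1 lost its call at 24 h with quantile normalization (adjusted p = 0.0974), without the intensity trend (0.0916) and with 3 of the 6 arrays left out in turn. SPRR2B had log2 1.40 (adjusted p = 0.0502). At 5 h the average called 0 genes with limma (549 with an unadjusted p under 0.05), with a highest of 2 in the other splits. All 100 splits meet a count of 0, so this says nothing about chance.

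STK26 and RAP2C are neighbours on the X chromosome among the genes tested, and both were lower in radioresistant tumours in all 3 conditions, with averaged log2 differences of -2.66 and -2.21. Loss of a larger segment in the radioresistant line may lower neighbouring genes too. The 10 flanking genes tested had a median of -0.257, between -0.461 and 0.0707, which argues against a larger loss that spans them, while a smaller loss, which may also take in genes that were not tested, stays open. MOSPD1 was the only flanking gene to pass (log2 -0.41, adjusted p = 0.0178).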
